A study of Homo sapiens with 8 samples.

How the data were processed

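RNA was measured in 8 samples of HUES8, an established human embryonic stem cell line, carried through a stepwise differentiation in suspension and taken at stage 5. Per the labels' protocols, small structures called buds were shaken off the spheroids and filtered away from the remaining bulks. Bulks came from 5 differentiation flasks (252, 261, 264, 270 and 274) and buds from 3 of them (264, 270 and 274). Polyadenylated RNA was selected, libraries were made with PrepX kits and sequenced as paired ends on an Illumina NextSeq instrument, per the labels' protocols.

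The values used are the expected counts per Ensembl gene that the authors deposited. Per the series design text and the submitters' processing notes, reads were aligned to GRCh38 with STAR and quantified with RSEM at default settings. The versions, the annotation release and the use of strand in counting are not given in the sources used here. RSEM divides reads that match several genes, so 11.5% of the deposited values were not whole, and the counts of near-identical genes such as PRSS1 and PRSS2, CELA3A and CELA3B, HSPA1A and HSPA1B, or HBG1 and HBG2 are uncertain as single values. Reads of a gene and an antisense partner cannot be told apart unless strand was used.

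The table held 58233 genes, of which 57392 (98.6%) were matched by Ensembl identifier to symbols and GRCh38 coordinates in GENCODE release 44. Expected counts were rounded to whole numbers. Library totals ran from 6083973 to 12508039 counts. Counting intervals and floors cover counting error only. The groups were compared with edgeR 4.0.16 in R 4.3.3, using TMM factors, its default expression filter by group (minimum count 10, minimum total 15), the quasi-likelihood F test and Benjamini-Hochberg adjustment, with a threshold of 0.05 and no covariate. Fold changes are buds over bulks on the log2 scale, with standard errors from the fit. CPM (counts-per-million) values use the TMM-scaled library sizes unless a share of all counts is named. The labels number the differentiation flasks separately, and all hold 1 cell line. The main fit treats the libraries as independent, though some flasks gave both samples. Its p-values therefore measure the spread between libraries of that line, not the spread of the difference within flasks.

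Gene lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule took 20 anchor genes, the 2 largest changes in each list with at least 3 members past the threshold, and the 5 largest rises and 5 largest falls among changed genes with at least 5 CPM in the higher group and the same direction in all 3 flasks that gave both samples. It left out Y-linked genes and XIST and gave 76 genes, of which 2 are not reported here. The 26 lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Counts of members adjusted over the list alone equalled those over all genes tested unless given. Shares of counts were compared with a two-sided exact permutation test over the 56 assignments of 8 libraries, which cannot give a p below 0.0179.

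Buds and bulks of flasks 264, 270 and 274 share a flask by their labels. Their deviations from the group means correlated at 0.123, 0.134 and 0.295 across genes, each above 0.1, so the flask numbers were taken to pair the samples. The 12 pairs of a bud and a bulk from different flasks ran from -0.245 to 0.194, and 2 of them were above 0.1: the bud of flask 274 with the bulk of 252 (0.194) and the bud of 264 with the bulk of 261 (0.134). The fit with flask as a block was an alternative, as were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and unscaled library sizes, other expression filters, flask as a random effect, the 3 flasks with both samples alone, stricter thresholds and leaving out each library in turn. Added after seeing the data were a correction for gene length, a fit without 3 ribosomal RNA genes, a fit without the bulks of flasks 252 and 264, hormone and granule shares without their most abundant gene, and lists for neurons, neural crest and glia, and gut epithelium. Of the pairs of libraries within a group, none matched within sampling noise: the lowest chi-square per gene was 8.6, between the bulks of flasks 270 and 274.

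The test was tried on simulated counts for 16641 genes with the means, library sizes and dispersions of the real data and 200 genes changed. It recovered 54.5% of genes changed by a log2 fold of 1 and 80.0% of those changed by 2, with mean estimates of 0.98 and 1.91, and 6.5% of its calls were unchanged genes. Far more genes changed in the real data, and no flask effect was simulated, so these rates need not hold for the real comparison.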

Results

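Expression was compared between buds (n = 3) and the bulks of the spheroids they were detached from (n = 5), to ask how the cell content of the outgrowths differed from that of the remaining spheroid. Bulks held 8235881, 7639516, 6083973, 10626052 and 9249475 counts in flasks 252, 261, 264, 270 and 274, and buds held 7477408, 10441456 and 12508039 in flasks 264, 270 and 274.

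SST and most secretory granule genes were higher in buds, and most genes of the cell cycle, of epithelium and of pancreatic progenitors were lower. SST, encoding the hormone somatostatin, rose from 933 ± 488 CPM in bulks (SD, n = 5) to 5733 ± 2251 CPM in buds (SD, n = 3). PDX1, a transcription factor of the pancreatic epithelium and of beta cells, was at 51.8 ± 8.90 CPM in bulks and 11.5 ± 3.26 CPM in buds. MKI67, a marker of proliferating cells, was at 67.7 ± 13.4 CPM in bulks and 10.2 ± 0.241 CPM in buds. Of 16641 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 7861 (47.2%) changed, 3894 of them higher and 3967 lower in buds, and 7698 had the called direction in all 3 flasks that gave both samples. The change was at least 2-fold for 2293 of the higher and 2076 of the lower genes. The first principal component held 70.3% of the variance and parted buds from bulks, while the bulk of flask 264 lay apart on the second, which held 9.4%.

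**Figure D1:**
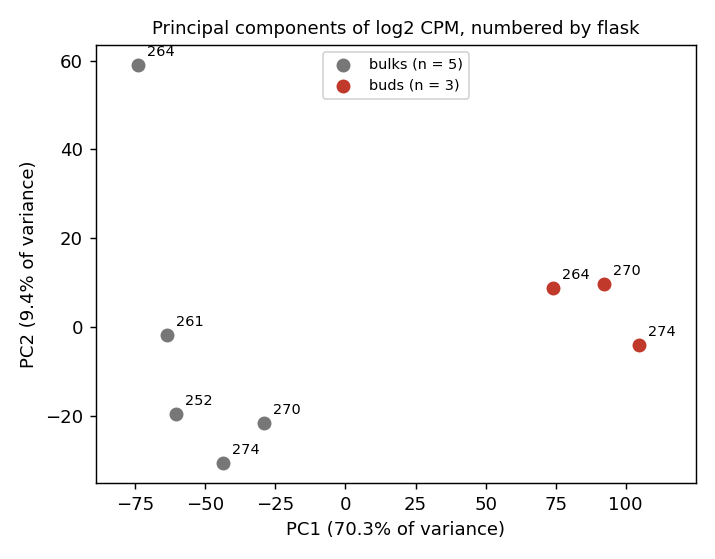
Principal components of log2 CPM for the 8 libraries, with PC1 (70.3% of variance) on the x axis and PC2 (9.4%) on the y axis; grey points are bulks, red points are buds and numbers are flasks. Buds lie at PC1 values from 74.03 to 104.9, bulks from -74.11 to -29.24, and the bulk of flask 264 lies at 59.12 on PC2.

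Of the 7 islet hormone genes, 5 rose and none fell. IAPP, the amyloid peptide released with insulin, rose by a log2 fold of 3.64 ± 0.45 (SE; edgeR adjusted p = 0.000109), and SST by 2.62 ± 0.40 (edgeR adjusted p = 0.000395). PPY, GHRL and PYY also rose, though under the flask block GHRL did not pass (edgeR adjusted p = 0.0620) and 4 hormone genes were higher. Neither INS (insulin, chromosome 11, 2159779 to 2161221, GRCh38) nor GCG (glucagon, chromosome 2, 162142882 to 162152404) passed: INS had a log2 fold change of 0.69 ± 0.51 (edgeR adjusted p = 0.292) and was higher in buds of 2 of 3 flasks, and GCG had -0.47 ± 0.51 (edgeR adjusted p = 0.480) and was higher in 1. In a fit without the bulks of flasks 252 and 264, chosen after seeing the data, GCG passed at -0.86 (edgeR adjusted p = 0.0413). Hormone genes made up 0.535 to 1.04% of counts in buds and 0.078 to 0.404% in bulks, a mean log2 difference of 1.70 (exact permutation test, p = 0.0357, n = 3 and 5). SST carried this difference. The other 6 hormone genes made up 0.108 to 0.219% in buds and 0.0387 to 0.272% in bulks, a log2 difference of 0.09 (exact permutation test, p = 0.893, higher in buds of 1 of 3 flasks). With SST included, of the tests that left out 1 library, only that without the bulk of flask 264 kept the exact p below 0.05. In the other 7 it ran from 0.0571 to 0.143. Leaving out 1 library also raises the smallest exact p possible, to 0.0286 without a bulk and 0.0476 without a bud. With SST the ranges of buds and bulks did not overlap, whichever library was left out.

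Genes of the secretory granule rose together, 14 of 16 over all genes tested and 15 adjusted over the list alone, with none lower. CHGA (chromogranin A) rose by 1.66 ± 0.34 (edgeR adjusted p = 0.00245), VGF by 4.03 ± 0.25 (1.17e-05) and PCSK1N, an inhibitor of prohormone convertase, by 3.25 ± 0.32 (3.58e-05). The granule share of counts was 1.09 to 1.80% in buds and 0.216 to 0.724% in bulks, a log2 difference of 1.72 (exact permutation test, p = 0.0179, n = 3 and 5). That exact p was 0.0571 without the bulk of flask 252, of 261 or of 274, where the smallest exact p possible is 0.0286. The ranges of buds and bulks did not overlap, whichever library was left out. Of 20 genes for exocytosis and excitability, 17 rose and none fell, among them the sodium channel gene SCN3A (3.30 ± 0.23). Camera gave adjusted p = 0.00844 for hormones, 1.02e-06 for granule and 1.5e-11 for exocytosis genes; with an estimated correlation the adjusted p was 0.323, 0.308 and 0.139. Transcripts of neurons were higher in the same libraries: of 11 tested genes of a neuron list written after the values were seen, 8 rose and none fell.

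Most markers of islet cell types rose. Of 16 beta cell genes 10 rose and 3 fell (camera adjusted p = 0.00583; 0.248 with an estimated correlation). The receptor gene GLP1R rose by 4.21 ± 0.41 (edgeR adjusted p = 3.05e-05) and ISL1, a transcription factor of islet cells, by 2.29 ± 0.34 (0.000308), whereas the transcription factor genes PDX1 (-2.18 ± 0.22, 3.54e-05) and NKX6-1 (-1.55 ± 0.35, 0.00404) fell, as did MNX1. Of 11 alpha cell genes 7 rose and 1, SMIM24, fell (camera adjusted p = 0.0113; 0.328 with an estimated correlation). SMIM24 fell by 4.43 ± 1.13 (edgeR adjusted p = 0.00655) from 2.54 ± 1.97 CPM in bulks, and was below the expression filter without the bulk of flask 252, 261 or 264. All 9 tested genes of delta, PP and epsilon cells rose (camera adjusted p = 6.03e-07; 0.103 with an estimated correlation), with SERTM1 at 4.63 ± 0.30 and RBP4 at 3.69 ± 0.35. Of 10 genes of serotonin-producing enterochromaffin-like cells, 5 rose and 1 fell, and adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.0544; 0.455 with an estimated correlation), with 3 higher under the flask block and also without the bulk of flask 252, the bud of 264 or the bud of 270. The set's adjusted p was 0.0275 to 0.0407 without the bulk or the bud of flask 270 or of 274. CBLN1 (3.06 ± 0.25) and DDC (2.21 ± 0.31) led them.

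Factors of endocrine commitment moved both ways, with 5 of 16 higher and 5 lower. NEUROG3, the factor that starts endocrine differentiation, fell by 1.45 ± 0.39 (edgeR adjusted p = 0.0110; 0.0784 under the flask block), from 199 ± 79.0 to 73.2 ± 31.7 CPM. DLL1, a Notch ligand, fell by 2.20 ± 0.25 and SCRT1 rose by 3.27 ± 0.44. NEUROD1 (0.11 ± 0.42, edgeR adjusted p = 0.853) and NKX2-2 (0.35 ± 0.43, 0.529) did not pass. FEV had 1.16 ± 0.44 (edgeR adjusted p = 0.0493; 0.343 under the flask block), and 0.59 (0.307) without the bud of flask 264. TPH1, the enzyme of serotonin synthesis, had 1.18 ± 0.43 (edgeR adjusted p = 0.0432; 0.173 under the block), and 0.79 (0.20) without that bud. The list gave camera adjusted p = 0.933, its median being 0.06 (-0.18 without the bud of flask 264), its mean 0.21 and its tested direction lower, and under the flask block 4 members were higher and 2 lower; without the bud of flask 274, 3 were lower.

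**Figure D2:**
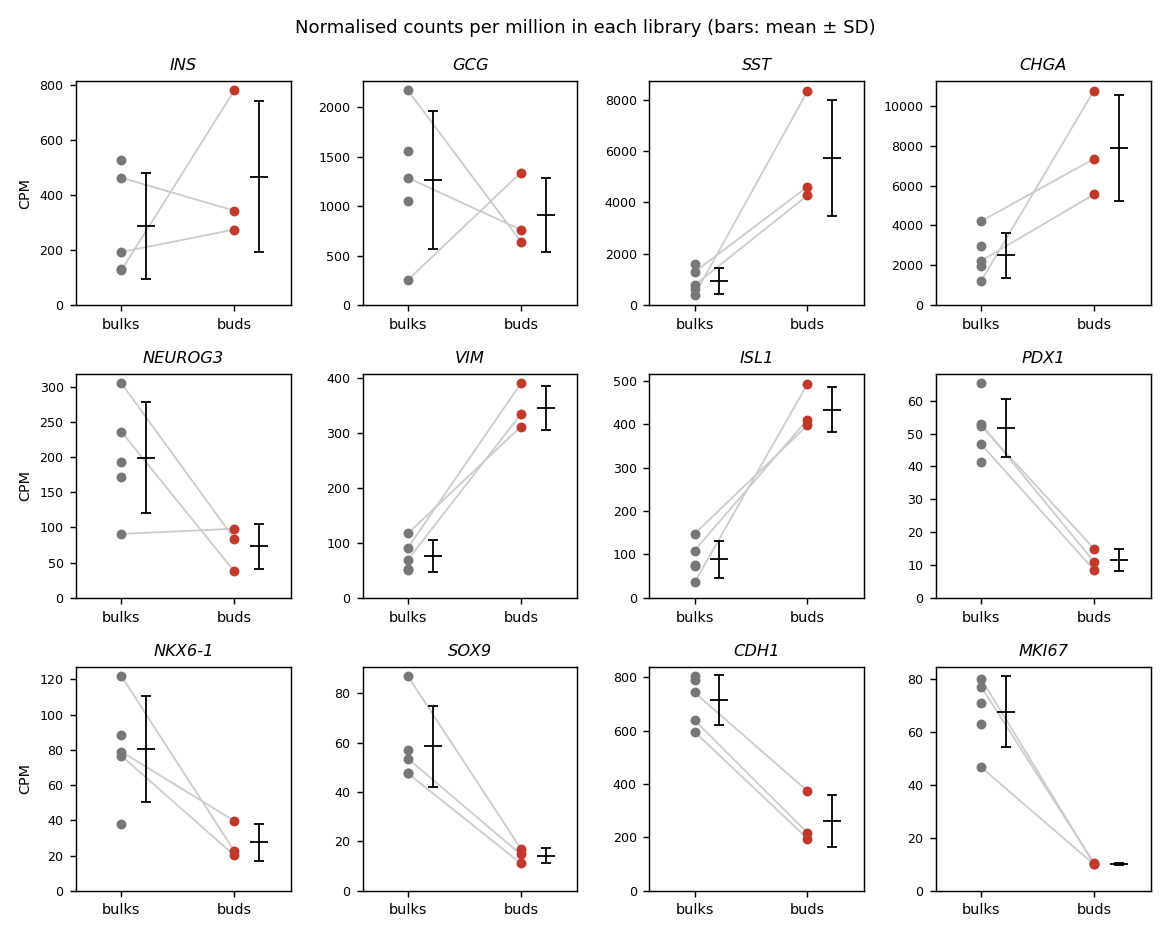
CPM of 12 genes (y axes, each from 0) in bulks (grey, n = 5) and buds (red, n = 3); grey lines join samples of a flask, and black marks are mean ± SD. SST, CHGA, VIM and ISL1 lie higher in buds of all 3 flasks, PDX1, NKX6-1, SOX9, CDH1 and MKI67 lower, while INS, GCG and NEUROG3 differ in direction between flasks.

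Progenitor genes of the pancreatic epithelium fell in 13 of 17 cases, and 2, ONECUT2 and PROX1, rose (camera adjusted p = 1.67e-05; 0.139 with an estimated correlation). MECOM fell by 3.44 ± 0.50 (edgeR adjusted p = 0.000286), ONECUT1 by 2.87 ± 0.20 (1.17e-05), SOX9 by 2.04 ± 0.24 (8.58e-05) and PTF1A by 1.84 ± 0.53 (0.0145). The PTF1A call was lost without the bud of flask 264 (edgeR adjusted p = 0.0512) or of flask 274 (0.0637). Of 8 tested acinar genes 7 fell (camera adjusted p = 0.00682, and 0.308 with an estimated correlation). The largest fall was that of SPINK1, a trypsin inhibitor, at -2.98 ± 0.43. The other 7 of the 15 acinar genes listed were below the expression filter. CELA3A, near its copy CELA3B in sequence, had -2.89 ± 0.94 (edgeR adjusted p = 0.0246; 0.0813 under the flask block), and 0.0574 without the bud of flask 264 and 0.0975 without that of 274. Of 11 duct genes 6 fell and none rose (camera adjusted p = 0.0802, 0.0165 under the block and 0.0147 without the bud of flask 264; 0.367 with an estimated correlation). The bicarbonate transporter SLC4A4 fell by 2.85 ± 0.47, and TFF2 had -2.80 ± 0.91 (edgeR adjusted p = 0.0249; 0.195 under the block, 0.10 and 0.0936 without the buds of flasks 270 and 274).

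All 26 cell cycle genes fell, by 1.25 to 2.85 (camera adjusted p = 2.43e-25; 0.0982 with an estimated correlation). MKI67 fell by 2.73 ± 0.20 (edgeR adjusted p = 1.23e-05), and TYMS and RRM2, which supply nucleotides for replication, by 2.85 ± 0.24 and 2.83 ± 0.22. In the Notch pathway 8 of 12 genes fell and 1, HEY1, rose, and adjusted over the list alone 9 fell and 2 rose (camera adjusted p = 7.45e-05; 0.0982 with an estimated correlation). The HEY1 call was lost under the flask block (edgeR adjusted p = 0.0894) and without the bulk of flask 252, 261 or 274 or the bud of flask 270. The receptor gene NOTCH1 fell by 3.36 ± 0.39 and the Notch target HES1 by 1.82 ± 0.18. Of 17 genes tied to YAP and TEAD, effectors of Hippo signalling, 12 fell and 2 rose (camera adjusted p = 0.000173; 0.272 with an estimated correlation), with YAP1 at -3.33 ± 0.37 and TEAD4 at -3.32 ± 0.37.

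Epithelial genes fell in 16 of 18 cases and none rose (camera adjusted p = 3.61e-10; 0.139 with an estimated correlation). CDH1 (E-cadherin) fell by 1.45 ± 0.22 (edgeR adjusted p = 0.000377), GRHL2, a regulator of epithelial identity, by 3.30 ± 0.26 and the tight junction gene CLDN4 by 3.06 ± 0.47. Basement membrane and integrin genes fell in 20 of 24 cases and 2, ITGA1 and ITGB1, rose (camera adjusted p = 1.02e-06; 0.0982 with an estimated correlation). HSPG2 (perlecan) fell by 3.56 ± 0.49 and ITGB6 by 3.35 ± 0.58. Genes of epithelial to mesenchymal transition, regulators and markers together, went both ways, with 3 of 9 higher and 3 lower (camera adjusted p = 0.684). VIM (vimentin) rose by 2.18 ± 0.25 and TGFBI by 3.05 ± 0.35. FN1 (fibronectin) fell by 3.31 ± 0.35, from 6532 ± 1454 to 658 ± 293 CPM. TWIST1, TWIST2 and PRRX1 of that list were below the expression filter. Of 24 guidance and chemokine receptor genes 11 rose and 5 fell, and adjusted over the list alone 12 rose and 5 fell (camera adjusted p = 0.0802; 0.0390 without the bulk of flask 264, 0.287 under the flask block and 0.308 with an estimated correlation). Under the block 8 were higher and 7 lower. The chemokine receptor gene CXCR4 rose by 2.42 ± 0.40 (edgeR adjusted p = 0.000667), PLXNC1, a semaphorin receptor gene, rose by 2.93 ± 0.32, and ACKR3, a second receptor for the ligand of CXCR4, fell by 2.95 ± 0.43.

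**Figure D3:**
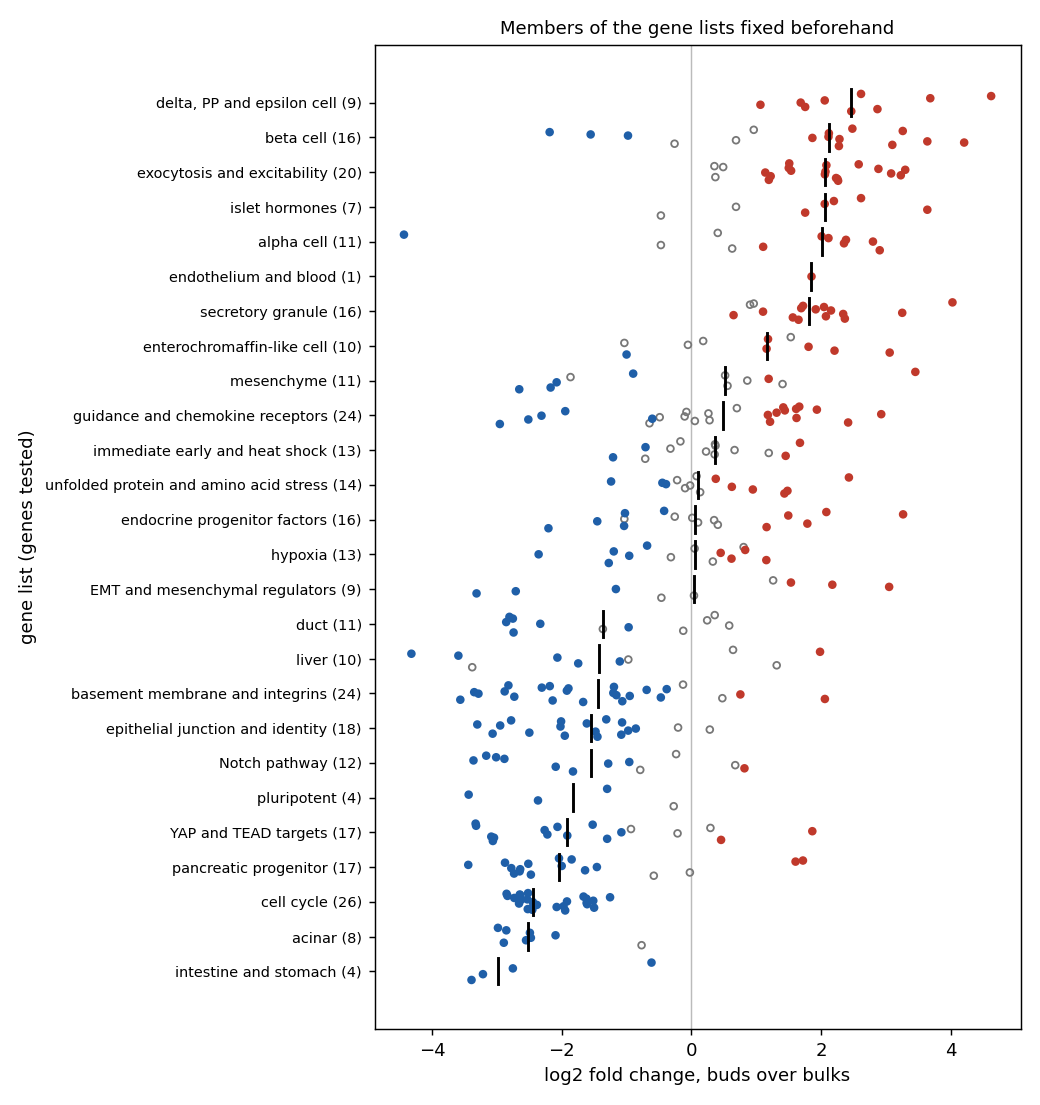
Log2 fold change, buds over bulks (x axis), of each tested member of the 26 lists (y axis, number tested in brackets); red and blue points rose and fell at an adjusted p below 0.05 with edgeR, open points did not pass and black bars are list medians. The cell cycle list lies wholly below 0 with a median of -2.44, and the delta, PP and epsilon list wholly above 0 with a median of 2.47.

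Lists for other cell types went in different directions. Of 11 mesenchyme genes 2 rose and 4 fell (camera adjusted p = 0.765), with a median of 0.52, a mean of -0.15 and a tested direction of lower; without the bud of flask 274, 2 fell, and without the bulk of 274 the median was -0.28. THY1 rose by 3.46 ± 0.43, and ACTA2 had -2.65 ± 0.71 (edgeR adjusted p = 0.00935; 0.0617 under the flask block, 0.0530 without the bud of flask 274). Of 10 liver genes 1 rose and 5 fell, and adjusted over the list alone 2 rose and 6 fell (camera adjusted p = 0.202; 0.0165 under the block and 0.541 with an estimated correlation), with 3 lower without the bud of flask 270 or of 274. The fibrinogen genes FGB and FGA had -4.32 ± 1.30 and -3.59 ± 0.73, and FGB had -2.82 without the bulk of flask 264. All 4 tested genes of intestine and stomach fell (camera adjusted p = 0.0414; 0.0738 with flask as a random effect, 0.0861 with genes of at least 5 CPM only and 0.308 with an estimated correlation). Without the bud of flask 270 or of 274, 2 passed. In the main fit the other 8 of the 12 genes of intestine and stomach were below the expression filter. SOX2 fell by 3.21 ± 0.39. CDX2, a factor of the intestine, had -3.39 ± 1.04 (edgeR adjusted p = 0.0203; 0.0744 and 0.0759 without the buds of flasks 270 and 274) and -2.05 without the bulk of flask 264. The adjusted p of FGB (edgeR, 0.0189) likewise reached 0.0761 and 0.0656. CDX2 and FGB stood at 71.3 and 150 CPM of all counts in the bulk of flask 264 and at most 8.64 and 19.3 CPM in the other bulks. Of 4 tested pluripotency genes 3 fell (camera adjusted p = 0.0289; 0.0690 with flask as a random effect, 0.0668 with genes of at least 5 CPM only and 0.161 with an estimated correlation), with LIN28A at -3.43 ± 0.42 and L1TD1 at -2.36 ± 0.42. The other 5 of the 9 pluripotency genes, POU5F1, NANOG, DPPA4, TDGF1 and UTF1, were below the expression filter, with at most 7 counts in any library. KDR, the 1 tested gene of endothelium and blood, rose by 1.85.

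No stress list passed camera. Immediate early and heat shock genes had 2 of 13 higher and 2 lower (camera adjusted p = 0.677), with JUNB at 1.68 ± 0.28 and DUSP1 at 1.46 ± 0.26, and under the flask block 4 higher and 2 lower. Also 4 were higher without the bud of flask 264 or the bulk of 274, and 1 was lower without the bulk of 252 or the bud of 264 or 270. Hypoxia genes had 4 of 13 higher and 5 lower, and 5 and 5 adjusted over the list alone (camera adjusted p = 0.619), with a median of 0.05 (-0.08 without the bud of flask 264), a mean of -0.19 and a tested direction of lower. Under the block 2 were higher, as without the bulk of flask 261 or 274 or the bud of 270. HK2 fell by 2.35 ± 0.39 and ADM by 1.27 ± 0.27. Genes of the unfolded protein and amino acid response had 6 of 14 higher and 3 lower (camera adjusted p = 0.325; fry adjusted p = 0.0118, higher). These counts were 5 and 1 under the block and without the bulk of flask 252, 261, 270 or 274 or the bud of 270 or 274. The ATF4 targets TRIB3 and CHAC1 rose by 2.43 ± 0.31 and 1.48 ± 0.23. Mitochondrially encoded genes made up 4.70 ± 0.087% of counts in buds and 4.16 ± 0.307% in bulks (SD, n = 3 and 5; exact permutation test, p = 0.0714); without the bulk of flask 261 or the bud of flask 270 the exact p was 0.0286 and 0.0476.

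Among changed genes with at least 5 CPM in the higher group and the same direction in all 3 flasks that gave both samples, the largest rises were those of VIP, a neuropeptide gene (6.84 ± 0.51), TRPC5, a cation channel gene (6.36 ± 0.57), the serotonin receptor gene HTR2A (6.30 ± 0.69) and MAB21L2 (5.80 ± 0.60), together with CDH12P2, a cadherin pseudogene whose reads could be shared with CDH12. CDH12P2 had no counts in any bulk and was at least 15.4-fold higher in buds, against a floor of 3 counts per library. By the same limits the largest falls, besides that of FGB (-4.32, and -2.82 without the bulk of flask 264), were those of GATA5 (-4.58 ± 0.58), the long non-coding RNA ENSG00000250899 (-4.25 ± 0.43), MUC16 (-4.20 ± 0.85) and RBBP8NL (-4.05 ± 0.36). MUC16 had -3.52 without the bulk of flask 264, where it stood at 77.1 CPM against 9.80 to 30.2 in the other bulks.

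Of the 26 lists, 15 passed camera with the preset correlation, 6 higher and 9 lower in buds, and none passed with an estimated correlation, where 8 had an unadjusted p below 0.05 and the smallest adjusted p was 0.0982; fry, which does not compare a list with other genes, gave 20. Bulk tissue counts do not part a change in the share of a cell type from a change within cells.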

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

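The fall of ribosomal protein genes, like the other patterns in this part, was noted after the data were examined. All tests of explanations were chosen after their values were seen, with exceptions for ribosomal protein genes only. These exceptions were the median with the length trend removed, set against length-matched lists, and the median under other scalings. The comparison with matched lists without a correction was not among them. Of 82 values examined in the 5 bulks, 7 had a sample far from the others (a gap over the range above 0.71, which chance gives in about 1 of 20 groups), and 5 of them lay in the bulk of flask 264. For genes the gap and range were taken on log2 CPM of all counts with a small constant added, not on the CPM printed below. For CELA3A, which had no counts in 1 bulk, the ratio depends on that constant.

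In the bulk of flask 264, CDX2 stood at 71.3 CPM against 7.62 to 8.64 in the other bulks (gap over range 0.944), and SOX9 at 86.6 against 46.9 to 55.0 (0.741). IAPP was lower there, at 0.329 against 1.96 to 3.40 CPM (0.748), as was CELA3A, with no counts against 1.94 to 5.08 CPM (0.764), and ENSG00000250899 was higher, at 11.7 against 5.11 to 6.49 CPM (0.711). The shift was broader than these genes: the medians of all 8 endocrine lists were lowest of the bulks there, at -1.13 to -0.55 (log2, against the mean of the bulks) where the other bulks had -0.30 to 0.99, and the acinar median was -1.35 against 0.19 to 0.43. This library had the fewest counts, but counting error alone is argued against for these 5 genes and the 9 lists. The exact 95% Poisson intervals of the genes and of the summed counts of the lists, 14 in all, lay outside the range of the other bulks. The 14 were taken because they stood apart there. No pair of libraries within a group matched within sampling noise, so an excess over counting error is not particular to this library. Mature gut epithelium is argued against by LGALS4, FABP1, FABP2 and PHGR1, which are abundant in that tissue and reached at most 0.329 CPM there, although CDH17 was at 6.08 CPM against at most 0.324; what accounts for the differences stays open, and no list of less mature CDX2-expressing cells was tested.

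In the bulk of flask 261, LIN28A stood at 17.8 CPM against 45.5 to 64.3 (gap over range 0.729). The share of ribosomal protein genes there was 5.41% of counts against 3.70 to 4.19% (0.713).

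Cytosolic ribosomal protein genes were lower in buds: 75 of 78 fell and 1 rose, with a median of -1.0, and their share was 2.13 ± 0.26% in buds and 4.28 ± 0.66% in bulks (SD, n = 3 and 5). Length was taken as the union of all annotated exons of a gene, with a median of 3064.5 bases for these genes. That length alone did not give such a fall, since 10000 lists of other genes matched in it had medians of -0.42 to 0.403 without a correction. Removing the trend on it, which moved genes by a median of 0.035 only, left -0.952. After that removal, 10000 length-matched lists had medians of -0.498 to 0.551. The union can exceed the length of the transcript expressed, so these values cannot decide on a bias by transcript length. Scaling between libraries is argued against because a scaling factor shifts all genes of a library alike and cannot set these genes apart from those lists. The median was at most -0.964 under 3 other scalings, but they could not have moved it far, since they left the median of all genes between -0.067 and 0.017. The summed share of these genes and their pseudogenes had a log2 ratio of -0.777 or lower, buds over bulks, in each of the 3 flasks, which argues against reads passing between them; no biological explanation was tested.

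Of the 56 splits of the libraries into 3 and 5, only the real one, 1 split, gave as many as 7861 changed genes, and the highest of the others gave 0 with edgeR. Every other split put buds and bulks together in a group, which widens the spread within groups, so few calls were likely there. The 56 splits weigh against chance only if libraries can be exchanged freely, which flasks shared by buds and bulks put in doubt. At an unadjusted p below 0.05 the real split gave 9000 genes and the others 24 to 4147. Where only the 8 splits that part all 3 flask pairs are compared, the real one gave 7861 genes and the 7 others 0, but 1 of 8 is a share of 0.125, and 8 splits are too few for a share under 0.05. With the pairs kept, the splits thus do not exclude chance.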

How the results depend on the processing

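The fits without length trend, without ribosomal RNA genes and without the bulks of flasks 252 and 264, and the shares without their most abundant gene, were added after seeing the data. The number of changed genes (7861) ran from 5391 to 9074 over the alternatives other than a test against a log2 fold change of 1, which called 2387 genes, 1295 higher and 1092 lower, since it asks for a larger change. With flask as a replicate block 6621 genes changed (3237 higher, 3384 lower), and 6358 of them were also called without it; 17 lists passed. With 1 library left out, 6201 to 7962 genes changed, 3147 to 3941 higher and 3036 to 4021 lower, and 15 or 16 lists passed. With flask as a random effect 13 lists passed and with genes of at least 5 CPM only 14; the lists of intestine and stomach and of pluripotency lost their calls in both. Camera with an estimated correlation passed 0 lists in place of 15. Leaving out 1 library gave log2 differences of 1.34 to 1.93 for the hormone share and 1.49 to 1.92 for the granule share, and 0.464 to 0.671 percentage points for the mitochondrial share; 3 paired differences alone (replicate block) gave 1.84, 1.73 and 0.711 with an exact p of 0.25, the smallest that 3 pairs allow. The hormone share without SST differed by 0.093 and the granule share without CHGA by 1.68. No named gene changed direction while past the threshold in either fit, though the sign of NEUROD1, past it in neither, turned to -0.12 under the flask block. Of 72 past the threshold, 63 stayed past it in all alternatives that tested them, but for the 2 stricter thresholds. Alternatives in which a gene was below the expression filter, as SMIM24 was in some, were not counted. Besides NEUROG3, FEV, TPH1, TFF2, CELA3A and ACTA2, the block changed no call of a gene taken by the naming rule; of the other list members named, it ended those of GHRL and HEY1. FEV did not pass with DESeq2 (adjusted p = 0.0841) or limma-voom (0.0541), nor CELA3A (0.178), TFF2 (0.0718) or FGB (0.0519) with limma-voom. Calls were also lost with upper-quartile factors (FEV 0.0579, TPH1 0.0503), with flask as a random effect (FEV 0.0598, TFF2 0.0820, CELA3A 0.156), in the 3 flasks with both samples alone (FEV 0.198, TPH1 0.0824, TFF2 0.124), without the bulks of flasks 252 and 264 (FEV 0.123, TPH1 0.103) and with the length trend removed (FEV 0.0542); the cause was not tested. Camera passed further lists with DESeq2 (enterochromaffin-like 0.0409, duct 0.0255), upper-quartile factors (enterochromaffin-like 0.0467), genes of at least 5 CPM only (enterochromaffin-like 0.0370), no expression filter (enterochromaffin-like 0.00652, duct 0.0221, guidance 0.0176) and without both of those bulks (guidance 0.0301). Without the bud of flask 264, MECOM, YAP1, CLDN4, HSPG2, ITGB6, ACKR3, FGA, FGB, CDX2, MUC16, ACTA2 and TFF2 had larger falls, from -3.56 (ACKR3) to -6.06 (FGB); PTF1A had -2.52 and CELA3A -3.60 without the bud of flask 270, and ACTA2 had -1.98 there. TFF2 had -2.20 without the bulk of flask 261. Scalings moved the median of all genes to between -0.067 and 0.017 and the higher share of calls to between 45.6 and 52.3%. At 6083973 to 12508039 counts per library, genes below the expression filter were not compared.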

Other observations

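Genes in this part were chosen after their values were seen, as were all its tests. All 7 tested HOXB genes, which pattern the body axis, rose in buds, from HOXB3 (2.30 ± 0.22, SE) to HOXB5 (5.56 ± 0.39), and all 7 did so under the flask block. Of 5 HOXA genes 2 fell and none rose, and of 2 HOXC genes 1 fell. Among potassium channel genes 42 of 64 rose and 7 fell, among GABA receptor genes 9 of 11 rose and none fell, and among synaptotagmin genes 11 of 15 rose and 1 fell. Claudin genes of tight junctions fell in 9 of 14 cases and none rose. The medians of these 4 families were 1.30, 3.47, 2.68 and -1.35.

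Neuronal transcripts were higher in buds: NEFL, a neurofilament gene, rose by 3.30 ± 0.30 (edgeR adjusted p = 2.61e-05), SLC17A6, a glutamate transporter gene, by 3.75 ± 0.29 (1.42e-05) and SLC18A3, an acetylcholine transporter gene, by 4.34 ± 0.43 (3.18e-05), while DBH, PHOX2A and POU4F1 did not pass. Neural crest or glial cells stay open: SOX10, FOXD3 and CDH19 reached at most 0.192 CPM in a bud, but S100B (at most 1.52 CPM in a bud), GFAP (2.30), TFAP2A (4.48) and TFAP2B (5.04) were each higher in buds of all 3 flasks. None of 5 tested genes of that list rose with edgeR and ERBB3 fell (list median 0.604), while 1 rose under the flask block. The union length of annotated exons is argued against as the whole cause, since 10000 lists of other genes matched in it had medians of at most 1.01 against 3.38 for the HOXB and neuron genes. The length of the transcripts expressed was not tested. Neurons in the buds may account for these genes (median 3.30 over the neuron list), but the list (17 genes, 11 of them past the expression filter) was written after neuronal genes had been seen to rise, and this cannot be told apart from transcription of these genes by endocrine cells, because each library pools all cells. The added gut list had 1 of 7 tested genes higher (KRT20) and 5 lower.

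The 3 genes inside the 18S ribosomal RNA repeats of chromosome 21 (8210384 to 8211306, 8393419 to 8394341 and 8437629 to 8438551, GRCh38) had identical counts in every library and together took 0.86 to 5.18% of counts in buds and 2.92 to 11.64% in bulks, without passing the test (log2 fold change -0.83 each, edgeR adjusted p = 0.264).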
